A study of Mus musculus with 13 samples.

How the data were processed

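The series holds 13 bisulfite sequencing libraries of sorted mouse myeloid cells in 4 groups: tumour-associated macrophages (TAMs, 2 libraries), mammary gland macrophages of healthy mice (MGMs, 3), and marrow monocytes of tumour-bearing (4) and of healthy mice (4). Per the labels' protocols, libraries were made by post-bisulfite adaptor tagging, in which adaptors are added after the conversion of unmethylated cytosines, and each was sequenced on its own HiSeq X lane with paired reads of 150 bp. Tumours were digested with collagenase A, healthy fat pads with collagenases II and IV, and marrow was flushed from leg bones, so tissue and preparation go together. The labels give an age of 8 weeks for tumour-bearing mice and of 12 to 13 weeks for healthy mice, while the treatment protocol gives 8 weeks as the age at injection and the design text calls the healthy mice age-matched. The age at harvest is therefore not given in the sources used here.

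Per the submitters' processing notes, the tools were Trimmomatic, BWA, Picard and MethylDackel 0.4.0 and the build was mm10; their settings are not given in the sources used here. The authors deposited, per the file headers, a table of coverage counts (reads covering each CpG in each library) and a table of the fraction of those reads that was methylated. Both tables hold 21867837 CpGs, and all value columns matched a sample by name. Methylated reads were recovered as coverage times fraction; all products were whole numbers within a tolerance of 1e-06. The 21353092 CpGs of chromosomes 1 to 19 and X were analysed, and 514745 CpGs of chromosomes Y and M were left out of the tests.

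The genome was divided into 500 bp tiles. A tile was tested if it held at least 3 CpGs and at least 10 reads in at least 2 libraries of every group, which 2808900 tiles did (91.5% of the 3071373 tiles with 3 CpGs or more). The tested tiles held a median of 5 CpGs, and 95.0% had 10 reads in all libraries. For each tile a binomial logistic model of methylated and unmethylated reads was fitted to all 13 libraries with 1 level per group, so that all groups share the estimate of the spread. Each comparison was a likelihood ratio F test, two-sided, with a Pearson dispersion moderated across tiles by the method of limma (prior of 37.8 degrees of freedom beside 9 residual ones, prior dispersion 1.24) and held at 1 or above. P-values were adjusted by the Benjamini-Hochberg method over all tiles of a comparison. A tile was called at an adjusted p under 0.05 and a difference of group means of at least 20 percentage points, and called tiles no more than 500 bp apart in the same direction were merged. The interaction, the TAM minus marrow difference less the MGM minus marrow difference, was tested on the logit scale with the same limits. Intervals and tests on reads take no account of reads copied by amplification beyond what the dispersion holds. Fits were written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and pyarrow 21.0.0; figures used matplotlib 3.10.9. Where limma on log2 ratios is named, the moderated test of limma was run in the same code on log2 of methylated over unmethylated reads with 0.5 added to each. An adjusted p called limma-moderated is that of the logistic model with its moderated dispersion, and not that of limma on log2 ratios.

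The code was tested on simulated data before use. Likelihood ratios of 300 tiles and the moderation were compared with R 4.3.3 and limma 3.58.1 and differed by less than 0.01. On chromosome 19 (73725 tiles), 200 tiles per size were lowered by 20, 30 or 40 points. In the comparison of TAMs with MGMs 33.0%, 87.0% and 96.5% were called, with 4 false calls. For TAMs against marrow these shares were 34.5%, 89.5% and 97.0% (1 false call), for MGMs against marrow 48.5%, 94.5% and 99.0% (6), for the marrow groups 42.5%, 97.5% and 100% (2), and for the interaction 25.5%, 66.0% and 81.0% (5). Of differences of 20 points, 38.5% to 84.0% passed the adjusted p, depending on the comparison, and the 20 point minimum left out part of these. For the marrow groups the simulation changed a larger share of tiles than the 0.00616% called in the data. The adjusted p depends on that share, so the simulated marrow rates do not hold for the real test.

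Genome-wide levels were the share of methylated reads over all CpGs, compared by exact permutation of the libraries, two-sided. Distances between libraries were medians of the absolute difference and means of a chi-square of the read counts, over tiles with 10 reads in all libraries, and principal components were taken on the 50000 tiles with the largest variance. The chi-square per tile was 1.23 or more between replicates of a group, above the 1 that sampling gives, so none was counted as a repeat.

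Genes came from a RefSeq table of gene extents of GRCm38, the assembly behind mm10, with neither strand nor exons. Promoters and sequence motifs were therefore not analysed here, and a gene's locus was its extent with 5000 bp on both sides, where the plan had named the upstream side alone. A gene list was tested by the number of its genes with a called tile against 10000 random lists of genes matched on the number of tested tiles in 20 bins (permutation, two-sided, Benjamini-Hochberg over 176 tests; the smallest p is 0.0002). Neighbouring genes of a list can share a tile. On 220 lists with shuffled calls 2.73% had a p under 0.05. The 22 lists held 486 genes, of which 484 matched the table. Genes that another list also holds numbered 6 in the macrophage core, 1 in tissue-resident macrophage, 7 in TAM-associated, 3 in immune suppression and checkpoints, 2 in inflammatory and NF-kB, 1 in MHC class II and antigen presentation, 2 in hypoxia and glycolysis, 6 in lipid handling, lysosome and phagocytosis, 9 in angiogenesis, matrix and adhesion, 8 in myeloid transcription factors, 2 in haematopoietic progenitor, 2 in bone marrow monocyte, 4 in neutrophil and granule and 2 in mast cell, basophil and eosinophil; interferon response, T cell, B cell, NK cell, epithelial and carcinoma, stromal, adipocyte and endothelial, erythroid and DNA methylation enzymes shared 0.

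The groups, comparisons, tests, gene lists and alternatives were chosen before the data were examined, apart from those named as chosen later. The genes named are those in or nearest to the 10 merged regions with the most called tiles per comparison and direction, and up to 3 members of each list with the most called tiles, each with the level of its called tile of the largest difference; since these tiles were chosen for their size, their differences are upper examples. Symbols of predicted genes were passed over, and values of some genes and regions that the rule names are not reported here. Alternatives were another tile length, read minimum, site minimum, difference minimum, chromosome set and coverage limit, the spread from the compared groups alone, differences measured from the median, limma on log2 ratios, a block for the replicate number and leaving out each library; thinning all libraries to the same number of CpG reads was added after seeing the data.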

Results

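DNA methylation was measured by whole-genome bisulfite sequencing in 13 libraries of sorted myeloid cells from female BALB/c mice. The tumour model was 4T1-luc, a luciferase-marked mouse mammary carcinoma line, injected at 100000 cells into a mammary fat pad. Tumour-associated macrophages (TAMs, n = 2) were sorted from the tumours as CD11b+ Gr1- F4/80+ cells. Mammary gland macrophages (MGMs, n = 3) were sorted from the fat pads of healthy mice by CD11b and F4/80. Marrow monocytes (CD11b+ Gr+ F4/80low) came from the leg bones of tumour-bearing mice (n = 4) and of healthy mice (n = 4). The Gr1 antibody binds Ly6C of monocytes and Ly6G of neutrophils, so this gate does not by itself separate those cells.

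Mean coverage per CpG on chromosomes 1 to 19 and X was 13.7 and 19.9 reads in the TAM libraries and 20.1, 20.8 and 9.68 reads in the MGM libraries. It was 17.5, 22.0, 20.9 and 20.6 reads in marrow monocytes of tumour-bearing mice and 24.1, 21.9, 20.6 and 15.5 reads in those of healthy mice. Between 94.2% and 95.9% of CpGs were covered, and between 72.7% and 89.8% had at least 5 reads. Methylation levels are percentages of reads that were methylated, given as mean ± SD over the libraries of a group. Differences are in percentage points. Coordinates are of build mm10. The annotation gave the extents of genes without strand or exons, so a region is placed inside a gene or at a distance from it. No label says that the replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

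At the most variable tiles the 13 libraries separated first by tissue. On the first principal component of the 50000 tiles with the largest variance (67.4% of the variance), TAMs lay at 13.9 ± 0.480 and MGMs at 19.7 ± 0.818. Marrow monocytes lay at -11.4 ± 0.896 in tumour-bearing mice and at -10.3 ± 0.816 in healthy mice. The second component (11.3%) set TAMs (11.9 ± 1.63) apart from MGMs (-6.44 ± 1.05). The median absolute tile difference was 4.31 to 5.61 points between a TAM and an MGM library, 4.23 between the TAM libraries and 3.25 to 4.25 between MGM libraries. Between a marrow library of tumour-bearing and one of healthy mice it was 3.31 to 4.11 points, against 3.39 to 3.70 and 3.38 to 3.92 within those groups. These differences include sampling noise. The mean chi-square per tile, which would be 1 from sampling alone, had a median over pairs of 2.16 between TAM and MGM libraries, against 1.37 within TAMs and 1.40 within MGMs. It was 1.35 between the marrow groups, against 1.27 and 1.35 within them. Over all tiles TAMs were no nearer to MGMs than to their marrow monocytes, with a chi-square of 2.08 and 3.97 to 4.77 points between a TAM library and one of marrow from tumour-bearing mice. The read-weighted level of all CpGs was 63.9% ± 1.31 in TAMs and 66.1% ± 0.179 in MGMs. It was 65.7% ± 0.398 in marrow monocytes of tumour-bearing mice and 65.6% ± 0.152 in those of healthy mice. TAMs lay -2.17 points from MGMs (exact permutation test, two-sided, p = 0.1, the smallest that 10 splits allow). They lay -1.79 points from their marrow monocytes (exact permutation p = 0.0667, the smallest that 15 splits allow). The TAM libraries differed in this: without replicate 1 the differences were -1.25 and -0.863 points, and without replicate 2 they were -3.10 and -2.71. With every tile counted once they were -3.32 and -1.48. MGMs lay 0.510 points above healthy marrow monocytes (exact permutation p = 0.0286, the smallest of 35 splits). As an unweighted mean over CpGs with at least 5 reads that difference was 0.847 points, with an exact permutation p of 0.171, and with every tile counted once it was 1.42 points. The marrow groups differed by 0.123 points (exact permutation p = 0.514), less than the spread between replicates, and by -0.423 points when every tile counted once.

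**Figure D1:**
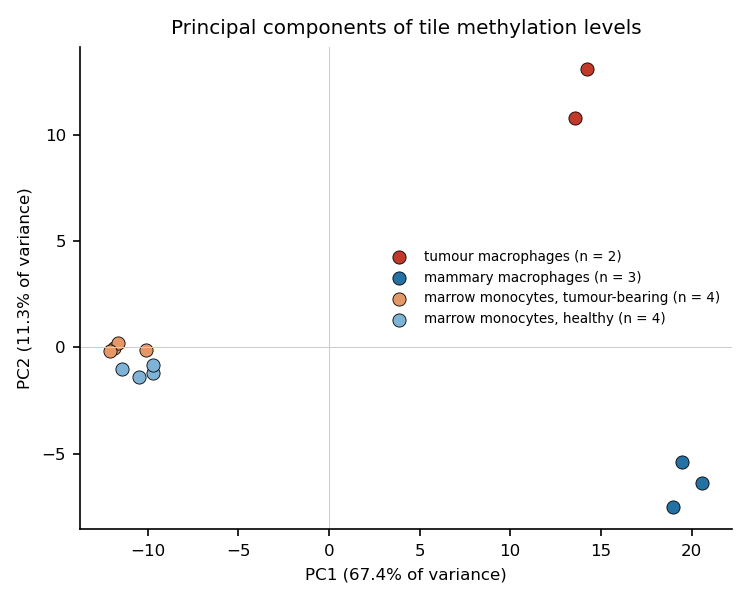
Scores of the 13 libraries on the first and second principal components of the 50000 most variable tiles of 500 bp (axes in component units, with the share of variance); each point is a library, coloured by group. TAMs and MGMs lie together on the first axis (means 13.9 and 19.7), apart from the marrow groups, and part on the second (11.9 and -6.44).

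TAMs were compared with MGMs to set macrophages of the tumour against those of the healthy gland. TAMs carried less methylation at genes of the inflammatory list (17 of 27 with a lower tile) and of the immune suppression list (13 of 20), both at a permutation adjusted p of 0.0014. At Socs3, an inhibitor of STAT3 signalling on the first list, a region on chromosome 11 from 117964001 to 117968000 that overlapped the gene stood at 23.9% ± 0.339 in TAMs (n = 2) and 71.1% ± 0.406 in MGMs (n = 3; limma-moderated adjusted p = 3.7e-23 at its lead tile). The checkpoint ligand gene Cd274, which encodes PD-L1, was at 30.4% ± 5.58 against 85.7% ± 3.46 in a tile inside the gene (chromosome 19, 29380001 to 29380500). In the other direction, genes of resident macrophages carried more methylation in TAMs: Mrc1, the mannose receptor CD206, was at 96.4% ± 1.96 against 41.7% ± 9.37 (chromosome 2, 14235501 to 14236000, inside the gene), with at least 18 reads in each library.

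Of 2808900 tested tiles of 500 bp, 19536 were lower and 5003 higher in TAMs, in 16664 and 4221 merged regions; 79.6% of the calls were lower. The median called difference was -25.3 points among lower and 27.0 among higher tiles. When differences were measured from the median of all tiles (-2.75 points), 13831 tiles were lower and 6372 higher, so that 68.5% were lower. With limma on log2 ratios 6516 and 1720 tiles were called, with a 30 point minimum 5131 and 1777, and with 1000 bp tiles 11243 and 2191. Without TAM replicate 2 the higher tiles came to 3333. Of the lower tiles 53.7% lay in a gene and of the higher 70.5%, against 47.6% of all tested tiles.

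The region with the most lower tiles in TAMs lay inside Pmepa1, which restrains TGF-beta signalling (chromosome 2, 173262501 to 173275000), with 23 called tiles and levels of 43.1% ± 5.14 in TAMs and 75.6% ± 2.17 in MGMs. Marrow monocytes stood near MGMs there, at 75.7% ± 0.649 with a tumour. At the gene of the chemokine Cxcl16 (chromosome 11, 70454001 to 70459000) TAMs were at 43.9% ± 2.52 and MGMs at 84.3% ± 2.73. Marrow was again high there (87.8% ± 0.705 with a tumour). Csf2rb, the shared beta chain of the receptors for GM-CSF, IL-3 and IL-5 (chromosome 15, 78327001 to 78331500), was at 25.4% ± 1.17 against 64.6% ± 4.08. Abi3, an actin regulator (chromosome 11, 95836001 to 95841500), was at 37.8% ± 0.152 against 80.8% ± 0.214. At other regions the marrow was low with TAMs. Inside Etv6, an ETS transcription factor of blood cells (chromosome 6, 134038001 to 134046500), TAMs were at 14.5% ± 1.91, marrow monocytes of tumour-bearing mice at 16.4% ± 0.814 and MGMs at 44.8% ± 1.30. Inside Meis1, a homeobox factor of blood stem cells (chromosome 11, 19007501 to 19011500), these levels were 19.7% ± 3.24, 7.80% ± 0.624 and 48.7% ± 0.767. The remaining named regions lay in Aopep and Htra3 and 136 kb from Haao.

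Among the regions higher in TAMs, Ahnak, a large scaffold protein (chromosome 19, 8993501 to 8997000), was at 77.9% ± 1.49 in TAMs and 33.4% ± 2.21 in MGMs, with marrow monocytes of tumour-bearing mice at 82.9% ± 0.850. F13a1, coagulation factor XIII A chain (chromosome 13, 37045001 to 37048500), was at 71.4% ± 0.971 against 33.7% ± 9.08. Clec10a, a C-type lectin of macrophages (chromosome 11, 70167001 to 70170000), was at 78.4% ± 2.76 against 45.9% ± 7.10. A region 253 bp from Maf, a transcription factor of macrophages (chromosome 8, 115697501 to 115703000), was at 69.9% ± 2.42 against 42.3% ± 7.38. A region 82.8 kb from Rbpj, the transcription factor of Notch signalling (chromosome 5, 53466001 to 53473000), was at 77.0% ± 3.12 against 46.2% ± 6.89. The others lay inside Emp1, Rgl1, Ap2a2, Rxra and Ttc7. Of the 5003 higher tiles, 4809 (96.1%) had a marrow level nearer to TAMs than to MGMs; of the 19536 lower tiles 9292 (47.6%) did.

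By gene list, 18 of 27 TAM-associated genes held a tile that was lower in TAMs than in MGMs (18 when adjusted over the list alone). Random lists of genes with as many tiles held 4.73 (permutation, two-sided, adjusted p = 0.0014, the smallest that the draws allow). Examples were Cxcl16, the fractalkine receptor gene Cx3cr1 (28.0% ± 0.973 against 80.5% ± 2.82) and arginase Arg1 (49.2% ± 12.4 against 91.8% ± 4.11). Of 20 genes of immune suppression and checkpoints, 13 held a lower tile (13 adjusted over the list alone, 5.18 in random lists, permutation adjusted p = 0.0014). Among them were Cd274, the interleukin 4 receptor gene Il4ra (23.9% ± 5.10 against 74.0% ± 5.08) and the PD-1 ligand gene Pdcd1lg2 (20.3% ± 7.29 against 81.7% ± 4.85). The permutation adjusted p was also 0.0014 for the next 4 lists. Lower tiles lay at 17 of 27 inflammatory and NF-kB genes (18 adjusted over the list alone, 4.70 in random lists) and 15 of 24 interferon response genes (15 adjusted over the list alone, 4.25). They lay at 15 of 22 genes of MHC class II and antigen presentation (15 adjusted over the list alone, 4.52) and 22 of 28 genes of hypoxia and glycolysis (22 adjusted over the list alone, 7.93). Il1b, which encodes interleukin 1 beta, was at 22.0% ± 4.21 in TAMs and 89.8% ± 5.41 in MGMs. Nlrc5, an activator of MHC genes, was at 39.7% ± 9.06 against 87.4% ± 4.23, and hexokinase Hk2 at 21.1% ± 2.5 against 60.5% ± 5.02.

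Lower tiles also met the list test at angiogenesis, matrix and adhesion genes (21 of 32, 21 adjusted over the list alone, 9.44 in random lists, permutation adjusted p = 0.0014), where the integrin Itgb5 held 36. They met it at neutrophil and granule genes (11 of 21, 13 adjusted over the list alone, 2.87, permutation adjusted p = 0.0014) and the macrophage core (14 of 25, 14 adjusted over the list alone, 4.85, p = 0.0025). Myeloid transcription factors passed with 22 of 44 (24 adjusted over the list alone, 12.0, permutation adjusted p = 0.0072). Lipid handling, lysosome and phagocytosis genes passed with 19 of 35 (19 adjusted over the list alone, 10.8, permutation adjusted p = 0.02). Haematopoietic progenitor genes passed with 12 of 20 (15 adjusted over the list alone, 6.57, permutation adjusted p = 0.033). With loci widened to 50000 bp on each side the adjusted p was 0.053 for angiogenesis, 0.45 for lipid handling and 0.56 for progenitor genes.

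Lower tiles did not pass for bone marrow monocyte genes (7 of 18, 9 adjusted over the list alone, permutation adjusted p = 0.33, and 0.021 at 50000 bp). They did not pass for tissue-resident macrophage genes (3 of 22, 3 adjusted over the list alone, permutation adjusted p = 1). Apart from the neutrophil and granule list, which passed, the lists of other cells that the gates could hold did not pass either. T cell genes with a lower tile were 11 of 23 (11 adjusted over the list alone), B cell genes 5 of 16 (5 adjusted over the list alone) and NK cell genes 3 of 13 (3 adjusted over the list alone). Epithelial and carcinoma genes were 10 of 26 (11 adjusted over the list alone) and stromal, adipocyte and endothelial genes 9 of 27 (11 adjusted over the list alone). Mast cell, basophil and eosinophil genes were 2 of 14 (3 adjusted over the list alone) and erythroid genes 2 of 14 (2 adjusted over the list alone). DNA methylation enzymes held 6 of 14 (6 adjusted over the list alone, permutation adjusted p = 1).

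Higher tiles in TAMs met the list test for tissue-resident macrophage genes, with 16 of 22 genes (16 adjusted over the list alone) against 1.73 in random lists (permutation adjusted p = 0.0014). Besides Mrc1 these included the endothelin receptor gene Ednrb (82.5% ± 0.505 against 12.6% ± 18.7, with as few as 10 reads in a library) and the haptoglobin-haemoglobin receptor gene Cd163 (89.0% ± 5.89 against 45.4% ± 7.12). Myeloid transcription factors (17 of 44, 18 adjusted over the list alone, 4.90 in random lists, permutation adjusted p = 0.0014) and lipid handling genes (14 of 35, 15 adjusted over the list alone, 4.90, p = 0.0025, and 0.067 at 50000 bp) also passed; the retinoid receptor gene Rxra, held by both lists, had 8 higher tiles.

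**Figure D2:**
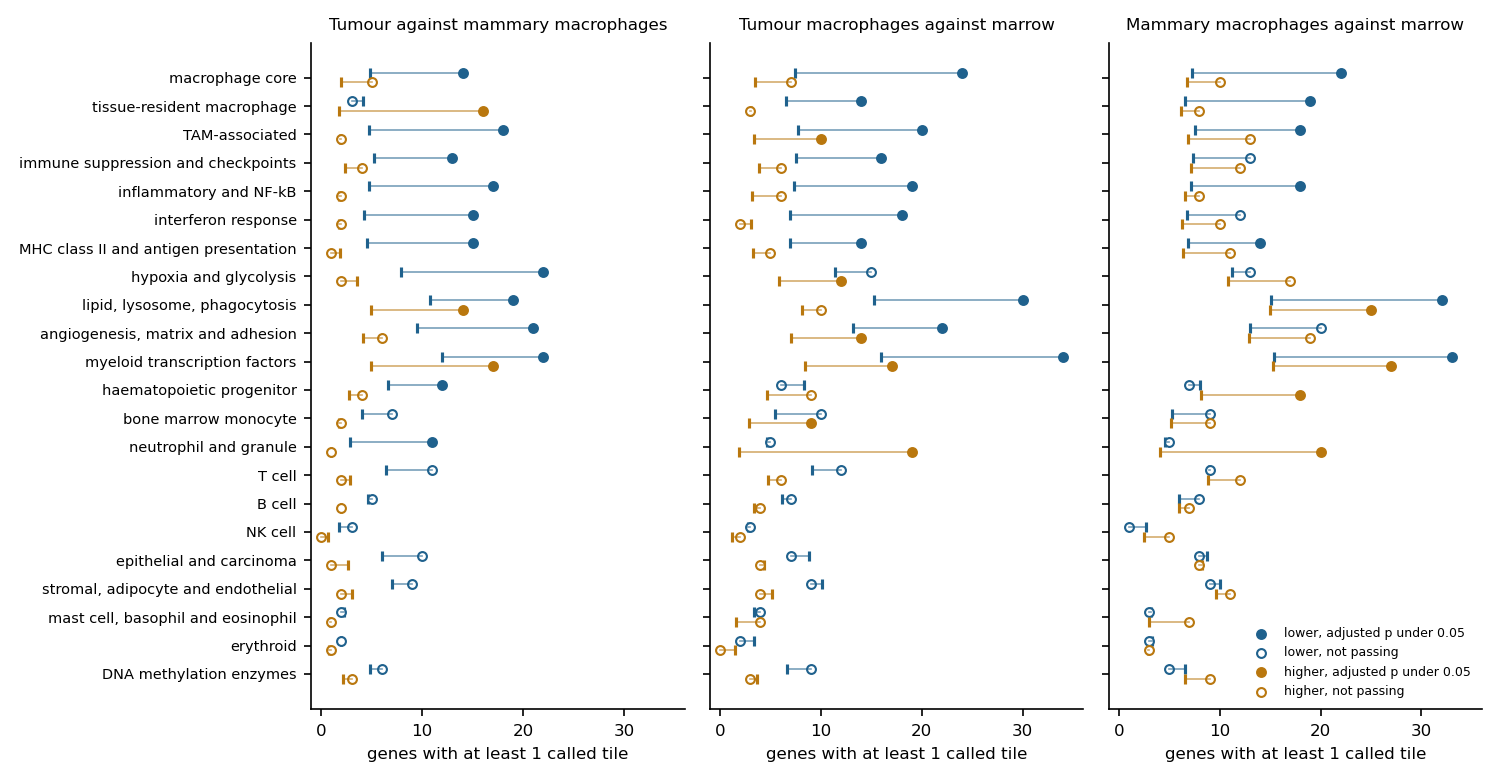
Number of genes with at least 1 called tile (horizontal axis) for each gene list (vertical axis) in 3 comparisons; circles are observed numbers, filled where the adjusted p was under 0.05, and ticks the means of matched random lists, blue for lower and orange for higher tiles. In TAMs against MGMs, tissue-resident macrophage genes stand out among higher tiles (16 genes, 1.73 expected) and TAM-associated genes among lower tiles (18 genes, 4.73 expected).

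TAMs were next compared with marrow monocytes of the tumour-bearing mice from the same kind of host. Macrophage genes were less methylated in TAMs. Complement genes C1qc and C1qb (chromosome 4, 136883501 to 136893000) were at 31.0% ± 0.852 in TAMs (n = 2) and 67.3% ± 1.17 in marrow monocytes (n = 4; limma-moderated adjusted p = 2.9e-14 at the lead tile), and prosaposin, Psap, a lysosomal protein (chromosome 10, 60278501 to 60284000), at 17.7% ± 2.68 against 72.1% ± 1.71. Granulocyte genes were more methylated: S100a9, a calprotectin subunit of neutrophils and monocytes (chromosome 3, 90692001 to 90695500), was at 73.5% ± 1.57 against 40.7% ± 2.26, and Gfi1, a repressor needed in granulocytes (chromosome 5, 107719001 to 107723000), at 84.5% ± 0.382 against 63.2% ± 3.30.

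In all 29361 tiles were lower in TAMs and 9923 higher, in 22430 and 8248 regions, with median differences of -29.3 and 26.6 points; 74.7% of calls were lower. A 30 point minimum left 13874 and 3378, tiles of 1000 bp gave 15838 and 4393, and limma on log2 ratios called 6090 higher tiles. Lower regions further included Sdc3, a heparan sulphate proteoglycan (chromosome 4, 130793501 to 130802000), at 33.2% ± 1.03 in TAMs and 72.9% ± 0.758 in marrow monocytes. Apobec1, a cytidine deaminase (chromosome 6, 122596501 to 122601500), was at 23.2% ± 0.989 against 78.9% ± 1.41, and Rin2, an endocytosis regulator (chromosome 2, 145860001 to 145865500), at 15.6% ± 0.233 against 48.8% ± 3.16. Rhbdf2, which controls release of TNF (chromosome 11, 116618001 to 116623000), was at 36.8% ± 0.373 against 68.6% ± 0.782, and the chemokine gene Ccl12 (chromosome 11, 82099001 to 82104500) at 40.7% ± 0.804 against 80.2% ± 1.24. Pmepa1, Cxcl16 and Csf2rb completed the lower regions. The higher regions lay inside Chd7, Tapt1, Pde2a, Cmtm7, Sun2, Dgkh, Chst11 and Igf1r, besides those at S100a9 and Gfi1. At Cmtm7 (chromosome 9, 114774001 to 114777500) TAMs were at 50.4% ± 2.25 and marrow monocytes at 6.51% ± 1.10.

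Of 25 macrophage core genes 24 held a lower tile in TAMs (24 adjusted over the list alone, 7.44 in random lists, permutation adjusted p = 0.0014). The efferocytosis receptor gene Mertk held 22 tiles, and its lead tile was at 23.7% ± 4.94 against 89.2% ± 2.40. The permutation adjusted p was 0.0014 for 6 further lists. Lower tiles lay at 30 of 35 lipid handling genes (31 adjusted over the list alone, 15.3 in random lists) and 34 of 44 myeloid transcription factors (34 adjusted over the list alone, 16). They lay at 20 of 27 TAM-associated genes (20 adjusted over the list alone, 7.69) and 16 of 20 immune suppression genes (16 adjusted over the list alone, 7.53). Inflammatory genes held 19 of 27 (20 adjusted over the list alone, 7.35) and interferon genes 18 of 24 (18 adjusted over the list alone, 6.91). Tissue-resident macrophage genes (14 of 22, 14 adjusted over the list alone, 6.58) passed at a permutation adjusted p of 0.0066. Angiogenesis genes (22 of 32, 22 adjusted over the list alone, 13.2) passed at a permutation adjusted p of 0.0076, which was 0.13 at 50000 bp. MHC class II genes (14 of 22, 14 adjusted over the list alone, 6.96) passed at a permutation adjusted p of 0.015. Ciita, the activator of MHC class II, was at 9.57% ± 1.90 in TAMs and 82.4% ± 2.45 in marrow monocytes. The interleukin 10 receptor gene Il10ra was at 10.1% ± 0.111 against 77.7% ± 2.74, and Zeb2, a transcription factor of myeloid cells, held 29 lower tiles.

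Higher tiles were found at 19 of 21 neutrophil and granule genes (19 adjusted over the list alone, 1.93 in random lists, permutation adjusted p = 0.0014). They lay at 9 of 18 bone marrow monocyte genes (9 adjusted over the list alone, 2.84, permutation adjusted p = 0.0035). Lower tiles lay at 10 genes of that list (10 adjusted over the list alone, 5.44, permutation adjusted p = 0.07, and 0.02 at 50000 bp). The permutation adjusted p was 0.0076 both for TAM-associated genes (10 of 27, 10 adjusted over the list alone, 3.38) and for myeloid transcription factors (17 of 44, 19 adjusted over the list alone, 8.41). Angiogenesis genes (14 of 32, 15 adjusted over the list alone, 7.04) passed at 0.022 and hypoxia genes (12 of 28, 12 adjusted over the list alone, 5.89) at 0.044. At 50000 bp the p for bone marrow monocyte genes, transcription factors and hypoxia genes was 0.08 and for angiogenesis 0.1. Mast cell, basophil and eosinophil genes (4 of 14, 4 adjusted over the list alone, 1.55, permutation adjusted p = 0.27) passed at that width, with 11 of 14 (11 adjusted over the list alone, 3.97, permutation adjusted p = 0.0019). Lower tiles at that width were fewer than in random lists at progenitor genes (7 of 20, 8 adjusted over the list alone, 14.4, permutation adjusted p = 0.0034). Gfi1 held 10 higher tiles and S100a9 held 8.

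MGMs were compared with marrow monocytes of healthy mice in the same way. Macrophage genes again carried less methylation in the tissue: C1qc and C1qb were at 36.3% ± 2.58 in MGMs (n = 3) and 68.5% ± 0.946 in marrow monocytes (n = 4; limma-moderated adjusted p = 3.6e-17 at the lead tile) and Psap at 22.1% ± 2.75 against 70.6% ± 1.20. Regions that were high in TAMs were low in MGMs, among them Ahnak (chromosome 19, 8990501 to 8999000; 24.6% ± 3.06 against 66.6% ± 1.19) and the region near Maf (42.3% ± 7.38 against 85.7% ± 1.56). Blood stem cell and granule genes were more methylated, with Meis1 (chromosome 11, 19007501 to 19012000) at 49.5% ± 0.676 against 12.3% ± 1.73.

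Lower tiles came to 26849 and higher tiles to 27240, in 20529 and 21412 regions, with median differences of -29.5 and 26.5 points; 49.6% were lower. Measured from the median of all tiles, 29941 were lower and 23270 higher, or 56.3% lower. A 30 point minimum left 12923 and 9354 and 1000 bp tiles gave 13486 and 13069. Another lower region lay inside Zeb2 (chromosome 2, 45101501 to 45107500; 26.2% ± 2.53 against 64.5% ± 1.72). A further one overlapped the end of the actin gene Actb (chromosome 5, 142899001 to 142905000; 30.1% ± 1.83 against 67.6% ± 1.14), and others lay inside Rin2, Rap1b and Ttc7 and near Rbpj. Higher regions lay inside Mapkapk3, a stress kinase (chromosome 9, 107281001 to 107288500; 67.8% ± 1.68 against 39.0% ± 2.60), and Etv6 (chromosome 6, 134038501 to 134044500; 48.3% ± 1.87 against 17.4% ± 1.03). Others lay inside Tle3, a corepressor (chromosome 9, 61375001 to 61381500; 68.3% ± 2.98 against 35.2% ± 0.559), Traf3, Tapt1, Chst11, Kif1b and Fam107b, and 107.5 kb from Irf2bp2.

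Lower tiles met the list test for 7 lists, 6 of them at a permutation adjusted p of 0.0014. They lay at 22 of 25 macrophage core genes (23 adjusted over the list alone, 7.24 in random lists) and 19 of 22 tissue-resident macrophage genes (19 adjusted over the list alone, 6.57). TAM-associated genes held 18 of 27 (18 adjusted over the list alone, 7.53) and inflammatory genes 18 of 27 (18 adjusted over the list alone, 7.13). Lipid handling genes held 32 of 35 (32 adjusted over the list alone, 15.1) and myeloid transcription factors 33 of 44 (33 adjusted over the list alone, 15.4). MHC class II genes passed at a permutation adjusted p of 0.0072 (14 of 22, 14 adjusted over the list alone, 6.88). Mrc1 held 27 such tiles, with 21.7% ± 8.74 against 88.2% ± 3.92 in the lead tile, and Zeb2 held 46.

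Higher tiles lay at 20 of 21 neutrophil and granule genes in MGMs (20 adjusted over the list alone, 4.05 in random lists, permutation adjusted p = 0.0014). They lay at 18 of 20 haematopoietic progenitor genes (18 adjusted over the list alone, 8.15, permutation adjusted p = 0.0014). Myeloid transcription factors passed with 27 of 44 (28 adjusted over the list alone, 15.3, permutation adjusted p = 0.0035). Lipid handling genes passed with 25 of 35 (26 adjusted over the list alone, 15, permutation adjusted p = 0.0066, and 0.27 at 50000 bp). The granule elastase gene Elane was at 45.0% ± 0.461 in MGMs and 2.09% ± 0.83 in marrow monocytes, and Ngp, a neutrophil granule protein, at 83.8% ± 3.87 against 34.2% ± 7.64. With loci of 50000 bp higher tiles also passed at TAM-associated genes (26 of 27, 26 adjusted over the list alone, 16.4, permutation adjusted p = 0.0019). So did the macrophage core (23 of 25, 24 adjusted over the list alone, 17, permutation adjusted p = 0.034) and angiogenesis genes (29 of 32, 29 adjusted over the list alone, 22.8, permutation adjusted p = 0.043). Lower tiles then passed at bone marrow monocyte genes (14 of 18, 15 adjusted over the list alone, 8.81, permutation adjusted p = 0.029).

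**Figure D3:**
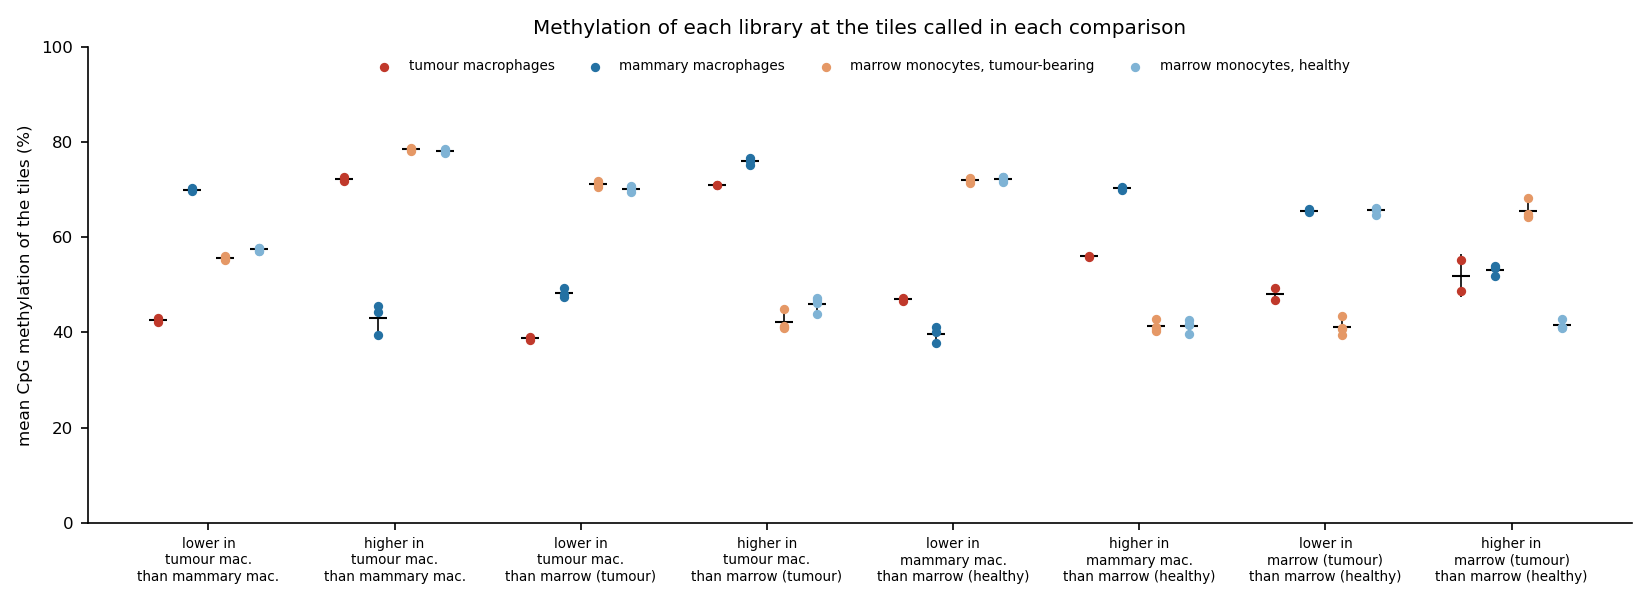
Methylation level (percent of reads) of each library, averaged over the tiles called in each comparison and direction; points are libraries, horizontal strokes group means and vertical strokes the SD. In tiles higher in TAMs than in MGMs the marrow groups stand at 78.5% and 78.2%, near TAMs (72.2%) and above MGMs (43.1%).

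The changes from marrow to tissue were shared in part between tumour and healthy gland, in comparisons that had no library in common. Of tiles lower in TAMs than in their marrow monocytes, 14931 (50.9%) were also lower in MGMs than in theirs, against 281 for independent lists. Of the higher tiles 7905 (79.7%) were also higher, against 96.2. Counted from MGMs, the shared tiles were 55.6% of the lower and 29.0% of the higher tiles. Opposite calls were few (46 and 4 tiles, against 285 and 94.8). Where the 2 changes differed was tested as an interaction, which called 10552 tiles with a lower and 3505 with a higher value in the tumour, 75.1% of them lower (67.1% when measured from the median of all tiles). The interaction count of 14057 fell to 253 with limma on log2 ratios, to 5311 with a 30 point minimum, to 8240 with 1000 bp tiles, to 8920 when all libraries were thinned to the same number of CpG reads and to 8898 without TAM replicate 2. At Irf8, a transcription factor of monocytes and dendritic cells (chromosome 8, 120738001 to 120742500), TAMs were at 23.3% ± 3.12 (n = 2) and their marrow at 67.7% ± 3.24 (n = 4). MGMs were at 51.0% ± 1.97 there (n = 3) and their marrow at 63.8% ± 2.21 (n = 4, limma-moderated adjusted p = 2.4e-07 for the interaction at the lead tile). Inside Gpr35, a receptor of myeloid cells (chromosome 1, 92974001 to 92977000), these levels were 23.9% ± 0.992, 70.1% ± 2.05, 63.6% ± 1.71 and 67.9% ± 2.57. A region 53.8 kb from Btc, a growth factor (chromosome 5, 91301001 to 91303500), went the other way, with 61.4% ± 0.750 in TAMs and 25.7% ± 3.77 in MGMs beside 65.0% ± 1.33 and 67.4% ± 4.76 in marrow.

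**Figure D4:**
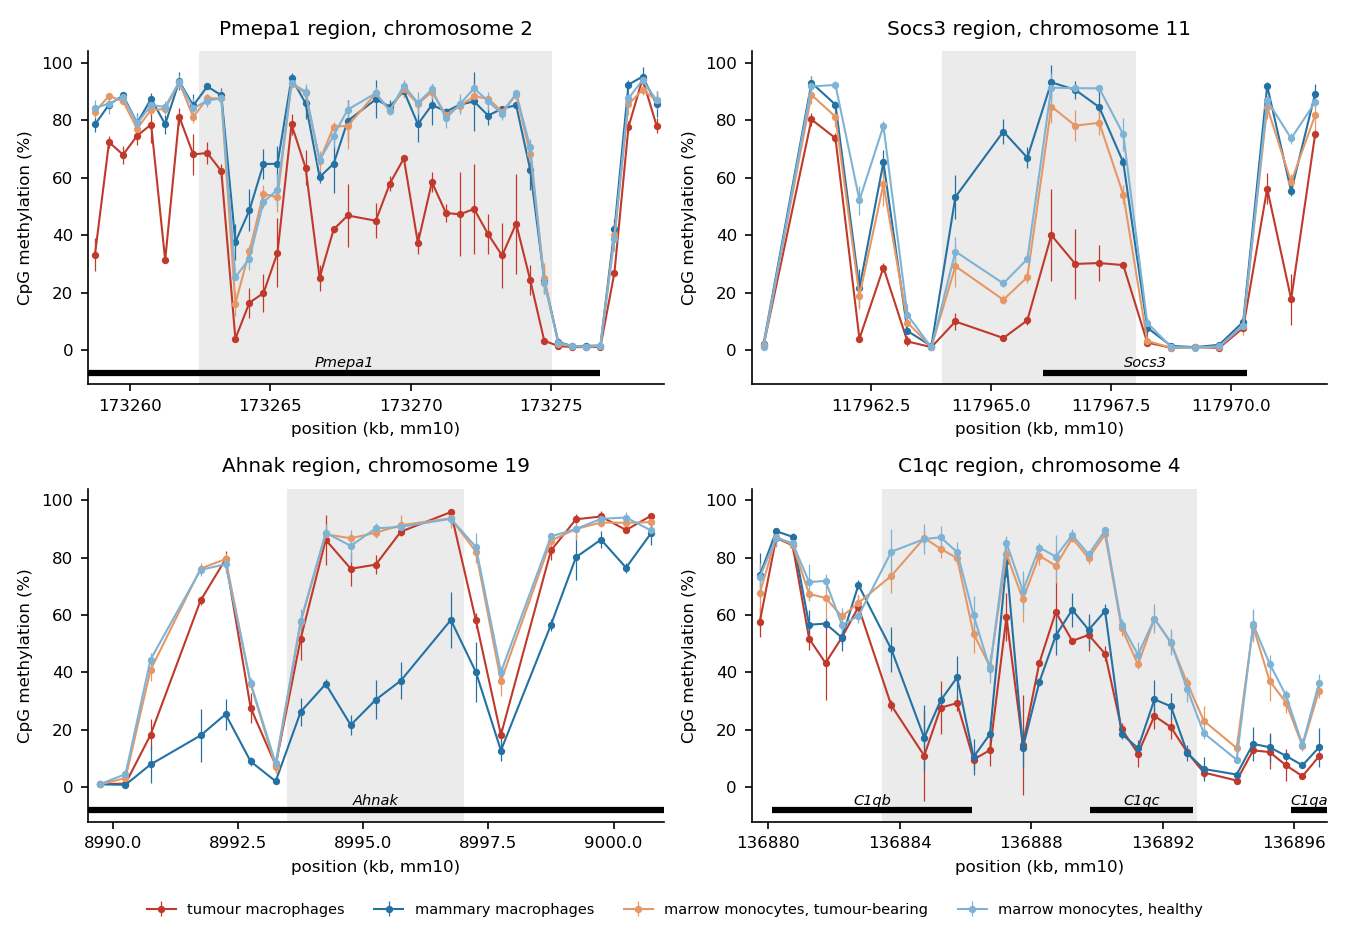
Methylation level (percent, vertical axis) of 500 bp tiles by position in kb (mm10, horizontal axis) in 4 named regions; points are group means with SD, grey marks the region and black bars the genes. TAMs fall below MGMs at Socs3 (23.9% against 71.1%) and rise above them at Ahnak (77.9% against 33.4%), while both lie below marrow at C1qc and C1qb (31.0% and 36.3% against 67.3%).

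Marrow monocytes of tumour-bearing mice were compared with those of healthy mice to set the marrow of hosts with a tumour against that of hosts without. The changes were few and most were losses. Inside Il4ra (chromosome 7, 125553501 to 125555000) the level was 28.6% ± 2.57 with a tumour (n = 4) and 51.9% ± 2.20 without (n = 4, limma-moderated adjusted p = 1.1e-12 in the logistic model at the lead tile). A region 3079 bp from Socs3 (chromosome 11, 117962001 to 117963000) was at 32.3% ± 5.93 against 61.4% ± 2.94, and Sbno2, a corepressor downstream of STAT3 (chromosome 10, 80073501 to 80075000), at 33.1% ± 1.83 against 58.4% ± 1.96.

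In all 150 tiles were lower and 23 higher, in 133 and 22 regions, with median differences of -23.3 and 24.6 points; 86.7% were lower. The labels do not settle the age of the groups at harvest, so age was not taken into account. Counts at an unadjusted p under 0.05 were 107209 and 66685, or 984 and 464 with a difference of at least 20 points. With limma on log2 ratios 0 tiles passed in either direction (80834 and 49766 at an unadjusted p under 0.05, of which 1059 and 523 differed by 20 points or more), a 30 point minimum left 14 and 1, and 1000 bp tiles gave 47 and 4. Further lower regions lay inside Aopep, an aminopeptidase (chromosome 13, 63241501 to 63244000; 57.8% ± 3.05 against 81.2% ± 2.55). They also lay inside Vmp1, an autophagy protein (chromosome 11, 86584001 to 86585000; 14.1% ± 1.10 against 40.2% ± 4.88), and overlapped the end of Ifitm1, an interferon-induced membrane protein (chromosome 7, 140969501 to 140970500; 43.4% ± 3.03 against 68.9% ± 3.87). Others lay inside Acadl and Auh, 7.73 kb from Slc30a4, and 29.9 kb from Lilrb4a, an inhibitory receptor of myeloid cells (chromosome 10, 51526501 to 51527500; 47.0% ± 6.84 against 76.9% ± 1.38). Among the higher regions, Hpse, which encodes heparanase (chromosome 5, 100716501 to 100717500), held 2 tiles and was at 66.1% ± 6.2 against 40.9% ± 3.16; the rest were single tiles, in or near Triqk, Rgs5, Ryr3, Ttc27, Ndufa4, Kif20b, Ano6, Ccdc54 and Etnk1.

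No gene list passed in the marrow. List members with a lower tile were Il4ra among immune suppression genes (1 of 20, 1 adjusted over the list alone, permutation adjusted p = 0.37, and 0.021 with loci widened to 50000 bp), Socs3 among inflammatory genes (1 of 27, 1 adjusted over the list alone, p = 0.31) and the cathepsin gene Ctsb among lipid handling and lysosome genes (1 of 35, 1 adjusted over the list alone, p = 0.81).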

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

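Of the tests in this part, the one for marrow monocytes mixed into the tumour sort was chosen after the result was seen.

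The change from marrow to tissue differed between tumour and healthy gland at 10552 tiles with a lower and 3505 with a higher value in the tumour, by the interaction test. In regions, TAMs less their marrow lay below MGMs less theirs by these differences: -32.9 points at Pmepa1, -37.2 at Abi3, -31.5 at Irf8, -41.0 at Cxcl16, -27.6 at Sash1, -32.0 at Otulinl, -54.4 at Socs3, -41.9 at Gpr35 and -41.4 at Etv6. They lay above by 27.7 points at Emp1, 33.1 at Rbpj, 21.8 at Ttc7, 45.2 at Ahnak, 32.4 at Clec10a, 32.5 at Rgl1, 24.6 at Rxra, 35.9 at Tuft1, 38.0 at Btc and 39.4 at F13a1.

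TAMs stood nearer to MGMs where methylation is lost from marrow to healthy gland than where it is gained. The TAM libraries covered 78.4% and 76.2% of the marrow to MGM difference at the 26849 lower tiles but 50.4% and 51.2% at the 27240 higher tiles. A mixture of marrow monocytes with cells at the level of MGMs would give equal shares. The shares differed by 28.0 and 24.9 percentage points, which argues against such a mixture as the sole cause. Marrow monocytes mixed with tumour macrophages that differ from MGMs could give unequal shares, so a part of marrow cells in the pattern stays open. The lower level of TAMs across the genome would also raise the losses. After the background difference of uncalled tiles was taken off the TAM levels, 19.5 and 18.3 points were left. This argues against the TAM shift alone as the whole cause. MGM levels were not corrected. MGMs lay above tumour-bearing marrow by 4.37 points in tiles at 20% to 40% in healthy marrow and by 1.82 at 60% to 80%. Such a shift would widen the gains and narrow the losses, so background differences of both groups together stay open. A pattern of cells that have made the losses but not all the gains is a hypothesis that these tests leave open. The different digestion, the labelled ages and the lack of a Gr1 gate for MGMs also stay open and could not be tested.

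Single libraries stood apart from the other 3 of their group, by the gap to the nearest library over the range, in 13 of 210 tests. Chance picks out about 1 in 20 groups, or 10.5 of these. Among tumour-bearing marrow libraries, replicate 2 was at 45.0% in the tiles higher in TAMs (the others 41.0% to 41.4%), and replicate 1 at 68.3% in the tiles higher than in healthy marrow (64.4% to 64.9%), at 41.1% in Igf1r (43.9% to 44.2%) and at 73.8% near Kif20b (82.5% to 83.6%). Replicate 3 was at 56.0% in the tiles with a lower interaction (56.7% to 56.8%), at 51.7% in Htra3 (54.4% to 54.7%), and near Rbpj at 83.0% (85.5% to 85.9%), 83.6% (86.1% to 86.2%) and 79.7% (84.5% to 84.8%) in 3 overlapping regions. Replicate 4 was at 37.3% at S100a9 (41.5% to 42.0%). Of the healthy marrow libraries, replicate 2 was at 35.5% in Tapt1 (37.7% to 38.2%) and 15.9% in Etv6 (17.8% to 18.1%), and replicate 4 at 53.6% in Traf3 (57.7% to 58.2%).

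In data outside the comparisons, reads on chromosome Y, which female mice lack, reached 0.0671% of a library's CpG reads.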

How the results depend on the processing

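Thinning to the same number of CpG reads was chosen after the result was seen; all other alternatives were planned. Counts stayed within 1.5 times the reported count under a read minimum of 30 per tile, a site minimum of 5 reads, chromosomes 1 to 19 alone, a coverage limit, differences measured from the median and the spread of the compared groups alone, which was not run for the interaction. Exceptions follow; where fewer tiles pass, the larger difference minimum or longer tiles do this by construction, and otherwise the cause was not tested. With 30 points the tiles lower and higher came to 5131 and 1777 (TAMs against MGMs), 13874 and 3378 (TAMs against marrow), 12923 and 9354 (MGMs against marrow) and 14 and 1 (marrow groups), the interaction to 5311 and the shared losses to 6760. Tiles of 1000 bp gave 11243 and 2191, 15838 and 4393, 13486 and 13069, 47 and 4, 8240 and 7400. With limma on log2 ratios TAMs against MGMs had 6516 and 1720 tiles, higher tiles of TAMs against marrow came to 6090, the marrow groups had 0 and 0 (80834 and 49766 at an unadjusted p under 0.05; the logistic model called 150 and 23) and the interaction 253. Limma on simulated tiles of chromosome 19 lowered by 20 and 30 points called 5.5% and 20.0% of the interaction and 27.5% and 82.5% of the marrow changes. The simulation changed a larger share of tiles than the 0.00616% called between the marrow groups, and the adjusted p depends on that share. The marrow rates are therefore not detection rates for the real test. Thinned libraries gave an interaction of 8920.

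Leaving out each library gave ranges of 14624 to 19655 lower and 3333 to 5659 higher tiles (TAMs against MGMs), 24664 to 29493 and 7211 to 10711 (TAMs against marrow), 24883 to 28047 and 25761 to 28456 (MGMs against marrow), 127 to 203 and 16 to 32 (marrow groups), 8898 to 15270 (interaction) and 12522 to 15203 (shared losses). The lowest values for TAMs against MGMs higher and for the interaction came without TAM replicate 2; a lone TAM library was assumed to vary like the other groups. With a library left out, the level of TAMs lay -3.10 to -1.25 points from MGMs and -2.71 to -0.863 from marrow, the ends coming from the TAM libraries. The level of MGMs less marrow was 0.847 over CpGs with 5 reads (exact permutation p = 0.171) and 0.412 to 0.587 with a library left out. The marrow groups' level difference changed sign, to -0.375 over CpGs with 5 reads and -0.423 over tiles, and was 0.0092 to 0.257 with a library left out.

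Deviations from the group mean were hardly correlated between same-numbered libraries (correlations of at most 0.006 in size). Within groups the chi-square per tile was 1.23 to 1.40, where sampling alone gives 1, so these deviations are largely sampling noise. The check therefore cannot tell whether the replicate number pairs the samples. With the number as a block the counts were 17184 and 4709, 26623 and 8723, 26426 and 26527, and 129 and 14, with 11691 for the interaction and 14215 shared losses. Of 10524 values of 442 named tiles over 24 settings, 567 no longer passed. Of the 442 tiles, 256 kept their call in every setting that tested them. The call was lost by 102 with limma on log2 ratios, 107 with a 30 point minimum and 116 with 1000 bp tiles. Of the values 0 changed direction, which says little. The tiles were chosen for large differences, and settings that alter only the test or its limits leave the difference as it was. Of 42 list tests that passed, 32 also passed with loci of 50000 bp, where 41 passed. Promoters, motifs, edgeR and regions of at least 2 tiles for motifs were not run.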

Other observations

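Of the tests in this part, those on macrophages mixed into the marrow sort, on depth, on the TAM and MGM levels of the marrow tiles, on read placement and on misread CpGs as the whole cause were chosen after the result was seen; the splits, the test at nearly full methylation and the test on epithelial genes were planned before.

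The list of DNA methylation enzymes did not pass in any comparison, and 2 of its members with called tiles are given here as values. Tet3, which oxidises methylated cytosine, held 9 tiles higher in TAMs than in MGMs, with 54.6% ± 5.27 (n = 2) against 20.8% ± 4.90 (n = 3) in the lead tile (chromosome 6, 83443501 to 83444000, inside the gene; limma-moderated adjusted p = 1.2e-09), and 68.2% ± 6.05 in marrow monocytes of tumour-bearing mice. Dnmt3a, a de novo methyltransferase, was at 16.1% ± 8.04 in TAMs and 34.2% ± 1.55 in MGMs against 85.2% ± 4.74 and 88.4% ± 3.09 in their marrow (chromosome 12, 3904001 to 3904500). CpG-dense tiles changed least in level: those with 17 or more CpGs stood at 43.8% in TAMs, 44.4% in MGMs and 44.1% in both marrow groups.

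The 150 tiles lower in marrow monocytes of tumour-bearing mice were exceeded by no other split of the 8 libraries: 1 of the 35 splits, the real one, called as many, and the highest other called 23 in either direction. A difference in total reads was not the cause of the count, since 125 tiles were called with all libraries thinned to the same number of CpG reads; how reads spread over sites was not matched. Mature macrophages in the marrow sort would lower the tiles that both tissue groups have lost, but these differed by 0.578 points (SE 0.523). Those tiles had to lie at least 20 points higher in these monocytes than in TAMs, a choice that favours such a result. TAMs lay 6.95 points above these monocytes at the 150 tiles, which were themselves chosen as low in the monocytes. Neither value therefore excludes mature macrophages in the sort. The same tiles were lower in TAMs than in MGMs by a mean of -17.5 points, against -3.73 in tiles matched on healthy marrow level and CpG number (-4.97 to -2.51; one-sided permutation p = 0.0001, the smallest of 10000 draws), with 136 of 150 below and 57 called (1.04 at the call rate of all tested tiles). A change in the host that reaches marrow and tumour alike is a hypothesis that stays open for the lower tiles, as does age. In the 23 higher tiles TAMs did not lie above MGMs (-1.15 points, 11 of 23 below). Their matched tiles stood at -4.18 (-7.94 to -0.553, one-sided permutation p = 0.049). Measured against matched tiles, as the lower tiles were, the 23 tiles therefore do not decide the matter.

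For the 23 tiles higher in marrow monocytes of tumour-bearing mice chance could not be excluded: 2 of 35 splits called as many in either direction, the real one and 1 with 23 lower and 2 higher tiles. A split and its mirror counted as 1, so splits with equal numbers of both groups on each side have no direction. The split with 23 lower tiles kept 3 of the tumour-bearing libraries together. Its tiles were thus lower on the side of those libraries, as the 150 tiles were, and may hold part of that difference. As ordered, the most higher tiles in any other split was 5. The count of 2 thus rests on tiles of the other direction. For MGMs against healthy marrow 1 of 35 splits, the real one, called 26849 lower and 27240 higher tiles. This is the smallest share that 35 splits allow, and it speaks for these libraries only, since the replicates may be technical. The highest other splits called 10433 and 14751, and those kept the MGM libraries together with a marrow library, a structure of the samples.

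TAMs were lower than MGMs across the genome (-1.25 points over reads without TAM replicate 1 and -3.10 without replicate 2). Read placement did not account for the lower level, since the difference was -3.32 points with every tile counted once. Counted so, the TAM libraries lay at 77.2% and 77.5%, closer together than the 63.0% and 64.8% over reads. The gap between these libraries thus depended on how reads were weighted. More methylated CpGs misread as unmethylated would lower full methylation most, but the difference was -4.12 points in tiles at 60% to 80% in healthy marrow and -1.58 points at 95% or more, which argues against it as the whole cause; this criterion was set after the planned test, at -1.58 against a limit of -1.67 (libraries -1.67 and -1.50), had left the matter open. Tumour cells in the sort, which CD45, CD11b and F4/80 should remove, cannot be told apart: epithelial and carcinoma loci differed from matched loci by 0.171 points, within the range of matched draws. A lower level of the macrophages themselves may be the cause, and was not tested apart from these. The labelled age, the digestion and the use of a Gr1 gate also differed between TAMs and MGMs. Their part in the lower level could not be told apart.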
